A study of Solanum lycopersicum with 6 samples.

How the data were processed

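RNA was extracted with Trizol from axillary buds of 2 tomato cultivars grown in a greenhouse, and BGI500 libraries were sequenced, per the labels' protocols. The labels put 3 libraries in the monomaker group and 3 in the compound raceme group, and their titles number the libraries 1 to 3 in each. The submitters' processing notes list HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5, without saying what each was used for. The authors deposited FPKM values for the 6 libraries in a table of 31139 rows, rounded to 2 decimals, per the file headers and values. FPKM is scaled to transcript length and to the library's total, which can shift all genes when abundant ones change; whether the authors scaled the libraries to each other is not given in the sources used here. The authors' deposited log2 ratio of compound raceme over monomaker, with a p-value and a q-value for each row, is in the same table, per the file headers; how it was computed is not given there. Chromosome names in the table are those of the SL3.0 genome, and 7639 rows carry coordinates. The annotation release is not given in the sources used here, and whether counting used strand is not given either.

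Of the loci, 5699 have 2 rows, 1 of which carries coordinates. Their FPKM values were summed, giving 25440 loci. For these rows the median SD within a cultivar was 0.29 on the log2 scale for single rows and 0.22 for their sum. This step was chosen after the structure of the table had been seen, and the rows as deposited were tried as an alternative.

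Because the table holds no counts, the test planned for counts did not apply and the test planned for normalized values was used. Loci with a mean of at least 1 FPKM were kept. Values were transformed to log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, and p-values were adjusted by the method of Benjamini and Hochberg. A locus was called at an adjusted p below 0.05. The fit had the cultivar as its only term. All fold changes are compound raceme minus monomaker on the log2 scale, and an adjusted p without another tool named is from this limma test. Depth per library is unknown without counts, so no counting interval or detection limit is given, and a value of 0 is reported only as listed at 0. On simulated data with 200 of 18802 loci changed, made for this comparison, the test called 18% of 2-fold changes and 90% of 4-fold changes, and 6.90% of its calls were unchanged loci. The simulated noise was independent for each locus and library. Differences between libraries that many loci share were not simulated, so these shares may not hold for the real calls. The simulation also gave fewer calls than the real data, 116 against 614. In the real data 4835 loci had an unadjusted limma p below 0.05. The adjusted threshold depends on how many loci change, so the share of changes found may differ as well.

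The table gives no gene names, and the RefSeq gene table used here (assembly SLM_r2.1) gives symbols without Solyc identifiers. Pairs of name and Solyc identifier were therefore taken from published locus assignments as recalled, not from the data sources. Each pair was then checked for whether RefSeq lists the symbol on the same chromosome, at a similar place among that chromosome's genes. A difference of place of up to 0.05 of the chromosome's genes passed, as did 1 within 0.02 of the difference shown by the nearest pairs. This check can reject a wrong pair but cannot tell close neighbours apart. Its tolerance was changed 3 times after it had been seen which names passed, before any gene's fold change was seen. Of 33 regulators of inflorescence and shoot branching, fixed by identifier before the data were examined, 26 passed; LIN, STM3, TMF and BL have no symbol in RefSeq and were kept as fixed, 1 lay elsewhere and was left out, and 2 have no row in the expression table used here. Of 187 further pairs, 130 passed and were used.

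Lists defined by product names had been fixed before the data were examined, but no source used here gives product names, so none of them could be matched. The further lists were written by identifier after the table had been opened and before any gene was tested. They cover Aux/IAA repressors, auxin transport and response factors, gibberellin, abscisic acid, jasmonate and defence, flavonoids, steroidal glycoalkaloids, sugar metabolism, homeobox and leaf patterning genes, light and clock, heat shock and fruit ripening, and trichome and floral organ genes as markers of other cells. The photosynthesis list was corrected and extended, and the cell cycle, cell wall and housekeeping lists were made, after a first fit had shown the number of calls, the library correlations and the most abundant loci of each library, which included photosynthesis loci. Fold changes of single genes had not been seen at that point. These 4 lists were therefore not fixed independently of the data.

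Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over 12 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance, were run beside it. With the estimated correlation, 0 of the 5 lists that passed kept their call. Counts adjusted over the list alone use only the tested members of that list. Called shares per chromosome were compared by two-sided Fisher's exact tests, and adjacent tested loci that were both called were counted against 10000 shuffles of the calls.

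Genes were named by a rule fixed before the data were examined. It takes the 10 called loci with the largest fold in each direction, with cultivars that do not overlap and at least 10 FPKM in the higher one. It also takes the called regulators, with S, AN, FA, SP, SFT, LS, BL, BRC1A and BRC1B whatever their result, and up to 4 called members of each other list. Last, it takes the 5 loci of highest mean that were listed at 0 in the other cultivar. Loci without a name were counted, and at most 2 identifiers per direction are given. Uncalled members of lists and those beyond the rule were named after their values were seen, to describe each list.

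Alternatives chosen before the data were examined were the library number as a block, quantile normalization, no filter, a filter of 10 FPKM in 3 libraries, a pseudocount of 0.1, each library left out in turn, and an estimated correlation in camera. Rows as deposited, scaling to equal totals, median-ratio scaling and leaving out both libraries numbered 1 were added after seeing the data. Alternatives that need counts were not run.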

Results

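Axillary buds, the shoots that form where a leaf joins the stem, were collected from tomato plants of 2 cultivars and profiled by RNA sequencing. The labels call the cultivars monomaker and compound raceme, and 3 libraries were made from each. The series asks which genes differ in expression between the buds of these cultivars. Expression was given as FPKM, fragments scaled by transcript length and library total, without read counts, so the sequencing depth of each library is unknown. FPKM values summed to 674654, 687303 and 686203 in the 3 compound raceme libraries and to 717108, 726262 and 750250 in the 3 monomaker libraries. Between 22755 and 23027 loci per library had a value above 0. Nothing in the labels says whether the libraries of a cultivar came from separate plants, so the p-values measure the spread between these libraries, which may be technical. Gene values below are mean ± SD in FPKM over 3 libraries, folds are on the log2(FPKM + 1) scale, which understates the change of low genes, and directions are compound raceme relative to monomaker.

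The first principal component held 56.4% of the variance and separated the cultivars. Compound raceme libraries scored -25.7, -54.3 and -55.9 on it, and monomaker libraries 10.9, 60.7 and 64.2, in the order of their numbers. Across loci, which are not independent replicates, the Pearson correlation of monomaker 1 with compound raceme 1 was 0.952. That exceeded its correlations with monomaker 2 (0.935) and monomaker 3 (0.917), whereas monomaker 2 and 3 correlated at 0.957 and the compound raceme pairs at 0.942 to 0.965.

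**Figure D1:**
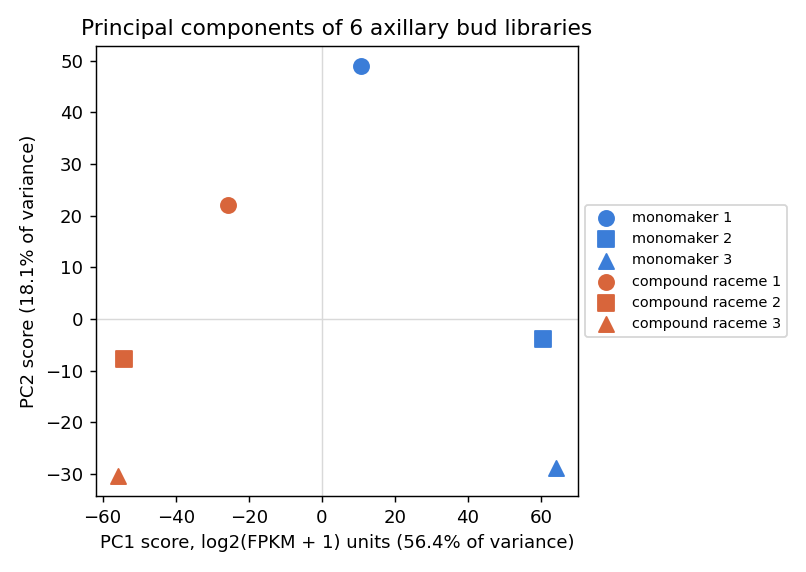
Scores of the 6 libraries on the first principal component (x axis, 56.4% of the variance) and the second (y axis, 18.1%) of log2(FPKM + 1) values, with color for the cultivar and shape for the library number. The cultivars lie on opposite sides of 0 on the x axis, and monomaker 1, at 10.9, lies closest to the compound raceme libraries.

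Among the genes given a name, the cell cycle genes CDKB1, CDKB2, CYCB1-2, CYCB2, CYCA1 and WEE1, the floral genes TM29, J2, EJ2, TM5 and TPI and the cell wall gene XTH1 fell in compound raceme buds, and the abscisic acid response factor AREB1 and the terpene synthase TPS5 rose. Of 18802 loci tested, 614 differed between the cultivars at an adjusted p below 0.05 in limma, 141 of them higher and 473 lower in compound raceme. At least a 2-fold change was present at 523 of these loci. At 5952 tested loci (31.7%) the values of the cultivars did not overlap. Chance gives 10% on average, but loci are not independent, so a single split can lie far from it. All 614 called loci were among them, which a call with 3 against 3 libraries nearly requires. Lower loci made up 77.0% of the calls, against 67.0% with quantile normalization (222 higher among 673). The count changed with the library left out, with 6 loci called without compound raceme 2, 7 without compound raceme 3, 8 without monomaker 2 and 15 without monomaker 3. It was 603 without compound raceme 1, with 384 of the 614 loci among them, and 2041 without monomaker 1. The excess of lower loci was lost in the first 4 of these fits, where they made up 0%, 0%, 12.5% and 46.7% of the calls, and was 64.0% in the last. None of the 14 called genes with a name kept its call in any of those 4 fits, and in each of the 4 their folds kept their direction. In those 4 fits 2844 to 3910 loci had an unadjusted limma p below 0.05, against 4835 with all libraries. Leaving out a library also leaves 2 against 3, so dependence on a library and loss of power were not told apart.

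Among the MADS-box genes in the lists, 5 fell in compound raceme buds and others had higher or lower values there without being called. TM29 (Solyc02g089200; chromosome 2, 51712263 to 51718095 of SL3.0), a SEPALLATA-class factor, fell from 5.25 ± 1.02 to 0.253 ± 0.0681 FPKM, a log2 fold change of -2.31 (SE 0.21, adjusted p = 0.0184). J2 (Solyc12g038510) and EJ2 (Solyc03g114840; chromosome 3, 66198734 to 66205172 of SL3.0) are related MADS-box genes whose joint loss is known to branch the tomato inflorescence. J2 had 3.50, 2.40 and 3.62 FPKM in monomaker and was listed at 0, 0.17 and 0.34 FPKM in compound raceme, a log2 fold change of -1.83 (adjusted p = 0.0214). EJ2 fell from 10.9 ± 3.01 to 3.65 ± 1.16 FPKM, with a log2 fold change of -1.35 and an adjusted p of 0.0454, which ranged from 0.0446 to 0.180 over 14 alternatives and stayed below 0.05 in 2 of them. In the list of floral organ genes, the SEPALLATA-class gene TM5 (Solyc05g015750) and the petal and stamen identity gene TPI (Solyc06g059970; chromosome 6, 38012678 to 38015713 of SL3.0) also fell, with log2 fold changes of -2.18 and -2.0 (adjusted p = 0.0193 each). TM5 had 5.18, 3.63 and 2.45 FPKM in monomaker, and in compound raceme it was listed at 0 in 2 libraries and had 0.05 FPKM in the other. TPI had 3.93 ± 0.909 FPKM in monomaker and 0.22 ± 0.151 FPKM in compound raceme. TM6 (65.2 ± 15.3 against 36.1 ± 4.96 FPKM, adjusted p = 0.0842) and TAG1 (2.54 ± 0.491 against 2.38 ± 0.356 FPKM, adjusted p = 0.866), the other 2 tested genes of that list, were not called. Of the MADS-box genes among the regulators, FUL1 (Solyc06g069430; 29.9 ± 11 against 17.4 ± 5.38 FPKM, adjusted p = 0.197) and STM3 (Solyc01g092950; 41.7 ± 3.37 against 26.0 ± 3.85 FPKM, adjusted p = 0.0696) had higher values in compound raceme. FUL2 (Solyc03g114830, log2 fold change -0.93, adjusted p = 0.0846), MBP20 (Solyc02g089210, -1.03, adjusted p = 0.0903) and LIN (Solyc04g005320, -1.27, adjusted p = 0.101) had lower values and were not called. MADS-box genes were not tested as a group. The floral organ list was made as markers of other cells. Whether the buds of the cultivars held a like share of floral tissue was not tested. Lower values of these genes therefore need not mean lower expression within the same cells.

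Other regulators of the inflorescence and of shoot branching did not pass the test over all loci. AN (Solyc02g081670), an F-box gene whose mutants carry highly branched inflorescences, had 1.84, 3.50 and 0.70 FPKM in monomaker and 0.05, 0.10 and 0.14 FPKM in compound raceme (log2 fold change -1.35, SE 0.37, adjusted p = 0.0956). BRC1B (Solyc06g069240), a TCP factor that restrains bud outgrowth, had 51.0 ± 6.65 FPKM in compound raceme and 23.6 ± 10.8 FPKM in monomaker (adjusted p = 0.113), and its relative BRC1A (Solyc03g119770) had 4.95 ± 0.997 and 3.55 ± 1.28 FPKM (adjusted p = 0.338). The LEAFY homologue FA (Solyc03g118160, log2 fold change -0.49, adjusted p = 0.330), the flowering repressor SP (Solyc06g074350, -0.67, adjusted p = 0.686) and the MYB gene BL (Solyc11g069030, -0.31, adjusted p = 0.794) were not called either; SP had a log2 fold change of 0.38 without compound raceme 1. Too low for the test were S (Solyc02g077390), the homeobox gene of the compound inflorescence locus, at 1.0 ± 0.442 FPKM in compound raceme and 0.963 ± 0.509 FPKM in monomaker, and LS (Solyc07g066250), needed for axillary meristems, at 0.783 ± 0.440 and 0.787 ± 0.387 FPKM. The florigen gene SFT (Solyc03g063100) was listed at 0.06, 0.06 and 0 FPKM in compound raceme and at 0, 0.24 and 0.43 FPKM in monomaker. Of the 24 tested regulators, 0 rose and 3 fell over all loci, and 2 rose and 9 fell when adjusted over the list alone; 18 had a fold below 0. As a set they were lower in compound raceme than other loci (camera, adjusted p = 0.00848), but not with an estimated correlation (adjusted p = 0.453), nor did they move 1 way on balance in fry (adjusted p = 0.141). The set also lost its call without compound raceme 1 (adjusted p = 0.188), without monomaker 1 (adjusted p = 0.0958) and in 2 other alternatives, the adjusted p reaching 0.414 over all 15.

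**Figure D2:**
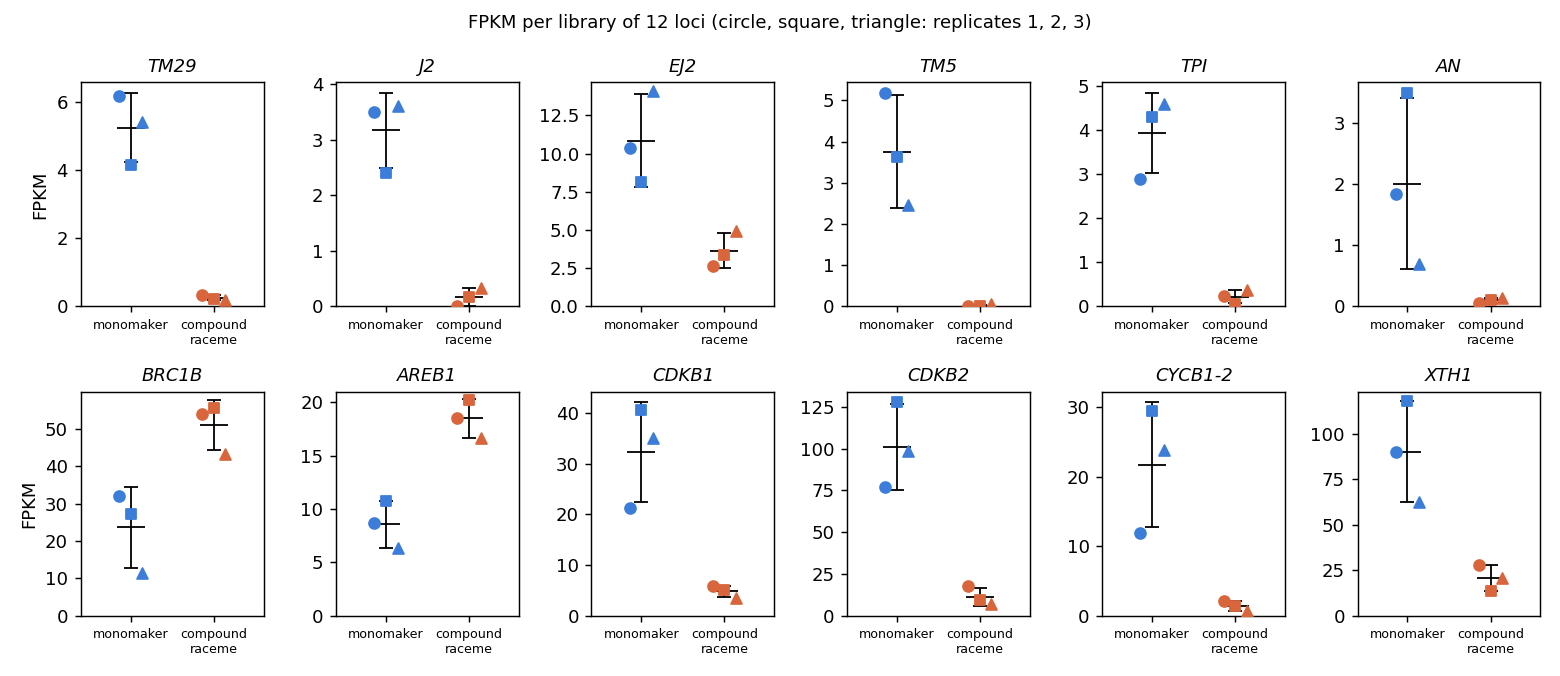
FPKM (y axes, linear, starting at 0 and scaled per gene) of 12 genes in 3 monomaker and 3 compound raceme libraries, with each point a library and each bar the mean ± SD. TM29, J2, EJ2, TM5, TPI, CDKB1, CDKB2, CYCB1-2 and XTH1 fell, AREB1 rose, and AN and BRC1B, with adjusted p of 0.0956 and 0.113, were not called.

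Cell cycle genes were lower in compound raceme buds. All 10 tested members had a fold below 0, and 6 of them fell, with 8 falling when adjusted over the list alone. CDKB2 (Solyc04g082840), a plant kinase active around mitosis, fell from 101 ± 25.6 to 11.4 ± 5.48 FPKM, a log2 fold change of -3.10 (SE 0.33, adjusted p = 0.0193). The related CDKB1 (Solyc10g074720) went from 32.3 ± 9.92 to 4.80 ± 1.11 FPKM, a log2 fold change of -2.49 (adjusted p = 0.0193). The mitotic cyclin CYCB1-2 (Solyc10g080950) fell from 21.7 ± 8.98 to 1.4 ± 0.721 FPKM and the cyclin CYCA1 (Solyc11g005090; chromosome 11, 66979 to 74099 of SL3.0) from 26.2 ± 5.33 to 6.2 ± 1.95 FPKM. CYCB2 (Solyc02g082820) and WEE1 (Solyc09g074830), a kinase that delays mitosis, also fell, with log2 fold changes of -2.04 and -1.43; they are named outside the selection rule, to complete the called members. The D-type cyclins CYCD3, CYCD3C2 and CYCD3C3 were not called, with adjusted p of 0.555, 0.0727 and 0.256, nor was CYCA2 (adjusted p = 0.134). The list was lower than other loci in camera (adjusted p = 3.97e-08), but not with an estimated correlation (adjusted p = 0.312), and its genes moved down on balance in fry (adjusted p = 0.0139). The photosynthesis list, described next, also had a lower mean in compound raceme, at 8.05 ± 0.55 against 9.85 ± 1.09 on the log2 scale (SD, n = 3). Leaving out compound raceme 2 or 3 or monomaker 2 or 3 left 0 of the 10 genes called, with list medians of -1.51 to -1.85 against -1.68 with all libraries.

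Photosynthesis genes had lower values in compound raceme than in monomaker 2 and 3, while monomaker 1 lay close to compound raceme. Averaged over the 22 tested members, log2(FPKM + 1) was 8.45, 7.43 and 8.27 in compound raceme 1 to 3 and 8.63, 10.16 and 10.76 in monomaker 1 to 3. The small subunit gene of Rubisco RBCS1 (Solyc02g063150), for example, had 639, 250 and 738 FPKM in compound raceme and 673, 3306 and 4636 FPKM in monomaker. The light-harvesting gene CAB12 (Solyc06g069730) had 46.0, 19.8 and 23.3 FPKM in compound raceme and 60.4, 440 and 722 FPKM in monomaker. All 22 members had a fold below 0, with a median log2 of -1.81, but 0 passed the test over all loci and 18 were lower when adjusted over the list alone. Camera placed the list below other loci (adjusted p = 1.76e-08), but not with an estimated correlation (adjusted p = 0.453), and fry did not pass (adjusted p = 0.143). Without monomaker 1 the test over all loci called 19 of the 22 lower. This list was extended after abundant photosynthesis loci had been seen, so it is not independent of the data, and the RBCS and CAB families hold near-identical copies among which reads may be split.

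**Figure D3:**
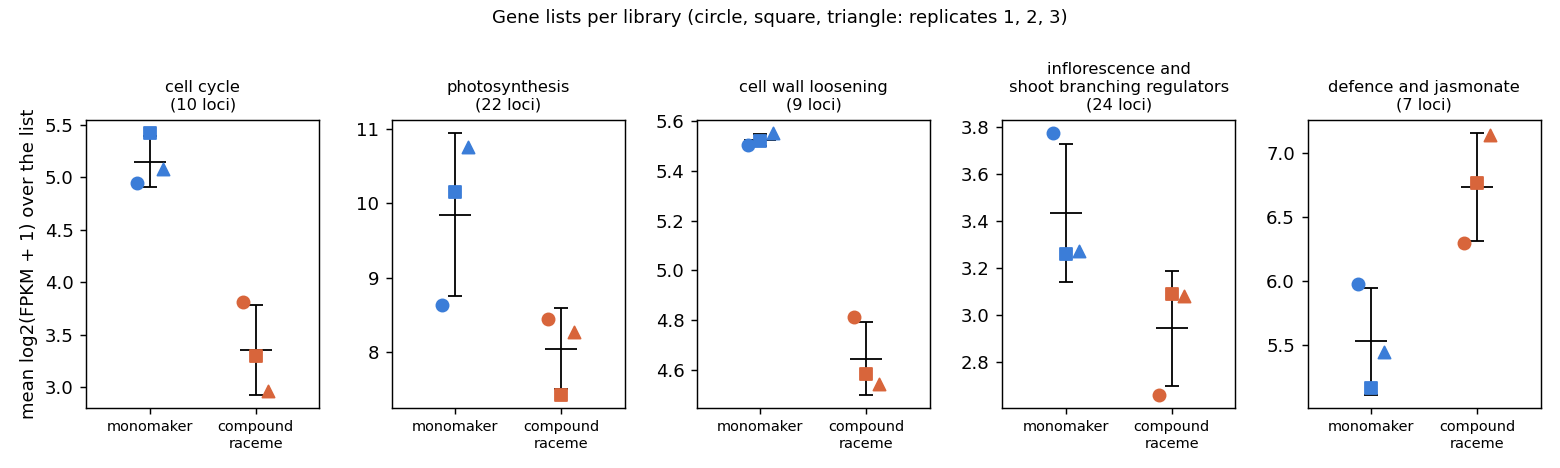
Mean log2(FPKM + 1) over the tested members of 5 gene lists (y axes, scaled per list and not starting at 0) in the 3 libraries of each cultivar, with each point a library and each bar the mean ± SD. Compound raceme values lie below those of monomaker for the cell cycle and cell wall lists, monomaker 1 (8.63) lies close to compound raceme 1 (8.45) for photosynthesis, and the jasmonate list lies higher in compound raceme.

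Genes that loosen the cell wall were lower in compound raceme on average. The xyloglucan endotransglucosylase gene XTH1 (Solyc01g099630) fell from 90.0 ± 27.8 to 20.6 ± 7.14 FPKM, a log2 fold change of -2.08 (SE 0.32, adjusted p = 0.0274). It was the only 1 of 9 tested members called over all loci, and 5 were lower when adjusted over the list alone. XTH7 (Solyc02g091920) had 21.3 ± 7.28 FPKM in compound raceme and 86.7 ± 44.4 FPKM in monomaker (adjusted p = 0.0518). In camera the list lay below other loci (adjusted p = 0.00174), but not with an estimated correlation (adjusted p = 0.279), and fry passed (adjusted p = 0.00579). The camera call at the preset correlation held in 14 of 15 alternatives, with an adjusted p of up to 0.0716.

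All 7 tested genes of jasmonate synthesis and response had a fold above 0 in compound raceme, but 0 passed the test over all loci and 6 were higher when adjusted over the list alone. JAZ2 (Solyc12g009220), a repressor of jasmonate response, had 275 ± 126 FPKM in compound raceme and 66.9 ± 44.1 FPKM in monomaker (adjusted p = 0.0877). The synthesis gene AOC (Solyc02g085730) had 165, 359 and 1267 FPKM in compound raceme and 140, 106 and 54.8 FPKM in monomaker (adjusted p = 0.135), and the factor MYC2 (Solyc08g076930) had 88.1 ± 8.54 and 46.9 ± 12.2 FPKM (adjusted p = 0.0703). The set was higher than other loci in camera (adjusted p = 0.000679), but not with an estimated correlation (adjusted p = 0.397), and fry did not pass (adjusted p = 0.0668). Without monomaker 1 the test over all loci called 2 of the 7 higher, and without both number-1 libraries 4 of the 7.

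AREB1 (Solyc04g078840; chromosome 4, 63586695 to 63591769 of SL3.0), a factor of abscisic acid response, rose from 8.58 ± 2.19 to 18.5 ± 1.80 FPKM, a log2 fold change of 1.05 (SE 0.20, adjusted p = 0.0454). It was the called member of 5 tested abscisic acid genes. The trichome terpene synthase TPS5 (Solyc01g105890) rose from 19.7 ± 3.85 to 57.0 ± 18.7 FPKM, a log2 fold change of 1.44 (SE 0.28, adjusted p = 0.0487). Each of these calls held in 6 of 15 alternatives, with adjusted p of 0.0303 to 0.191 for AREB1 and of 0.0118 to 0.183 for TPS5.

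The other lists of at least 5 tested members did not pass camera, and AREB1 was the only called gene in them. Of 14 Aux/IAA repressors of auxin response, 11 had a fold below 0, and camera gave an adjusted p of 0.0517, which ranged from 0.0128 to 0.301 over 15 alternatives and passed in 5 of them; 1 was lower when adjusted over the list alone. IAA9 (Solyc04g076850) had 129 ± 22.7 FPKM in compound raceme and 237 ± 20.6 FPKM in monomaker (adjusted p = 0.0521). Auxin transport and response factors (12 loci, adjusted p = 0.153, passing in 1 of 15 alternatives), the homeobox and leaf patterning list (6 loci, adjusted p = 0.284), flavonoid synthesis (7 loci, adjusted p = 0.393) and abscisic acid genes (5 loci, adjusted p = 0.393) did not pass camera. Nor did the list of steroidal glycoalkaloid genes (6 loci, adjusted p = 0.910, median log2 -0.20, mean -0.03) or that of sugar metabolism (5 loci, adjusted p = 0.910, median 0.17). LA (Solyc07g062680), a TCP gene of leaf form in the patterning list and among the regulators, had 10.6 ± 4.03 FPKM in compound raceme and 32.2 ± 8.98 FPKM in monomaker (adjusted p = 0.0513).

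The loci with the largest folds carry no name in the sources used here. With values of at least 10 FPKM in the higher cultivar, 100 called loci were higher and 305 lower in compound raceme. Solyc11g005080 had 15, 15.5 and 19.4 FPKM in compound raceme and was listed at 0 in all 3 monomaker libraries (adjusted p = 0.000715). Solyc12g010233 rose from 0.157 ± 0.0757 to 18.7 ± 1.88 FPKM, a log2 fold change of 4.08 (SE 0.16, adjusted p = 0.000715). Solyc01g074000 had 159, 588 and 343 FPKM in monomaker and 3.81, 6.04 and 0 FPKM in compound raceme, a log2 fold change of -6.62 (adjusted p = 0.0193). Solyc04g077130 had 18.1, 124 and 90.0 FPKM in monomaker and was listed at 0 in all 3 compound raceme libraries (adjusted p = 0.0193). The first 2 kept their calls in 14 of 15 alternatives, and the other two in 10 of 15.

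Called loci lay on all 12 chromosomes. The called share ran from 2.58% on chromosome 12 to 4.07% on chromosome 11. With higher and lower calls pooled, no chromosome differed from the rest in a two-sided Fisher's exact test (lowest adjusted p = 0.568). The directions were not tested apart. Chromosome 4 held the most higher loci, 26 of its 1542 tested loci, against 18 of 2382 on chromosome 1. Neighbouring loci were called together more often than shuffled calls, with 40 adjacent pairs, 32 of them in the same direction, against a mean of 19.3 and a highest value of 36 in 10000 shuffles (permutation p = 1e-04, the smallest these can give). The fullest window of 20 loci held 5 called loci, equal to the median of the fullest windows in 1000 shuffles. Adjacent pairs numbered 0 or 1 without compound raceme 2 or 3 or monomaker 2 or 3, fits with few calls. They were 26 without compound raceme 1 (603 calls) and 279 without monomaker 1 (2041 calls). Such pairs rise with the number of calls, and these fits were not set against shuffles. The 279 pairs therefore do not show stronger clustering.

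In the authors' deposited table, 3159 rows had a q below 0.05, 1100 higher and 2059 lower in compound raceme. Of the 614 loci called here, 603 (98.2%) had such a row in the authors' deposited table, all 603 with the same sign. In lists without a call here, the authors' deposited table has a row at that q for 20 of the 22 photosynthesis genes, all 20 lower, and for 5 of the 7 jasmonate genes, all 5 higher, among them CAB12 (q = 7.3e-06) and JAZ2 (q = 0.00266). It also has such a row for 4 of 14 Aux/IAA genes, all 4 lower, and for 2 of 12 auxin transport and response factors, 1 higher and 1 lower. The patterning (lower), heat shock (higher) and ripening (higher) lists have 1 such gene each. For the cell cycle list the authors' deposited table has such a row for 8 of 10 genes, against 6 called here, and for the regulators for 9 of 24, against 3. AN is 1 of these 9, at a log2 fold of -3.29 (q = 0.000115) in the authors' deposited table. BRC1B is the only higher 1 of the 9, at 1.05 (q = 0.0262) on the row with coordinates and 0.0166 (q = 0.9996) on the other. For TM29 the authors' deposited table gives -4.32 (q = 1.72e-08) on the row with coordinates and -1.76 (q = 0.157) on the other.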

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

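Rows as deposited, equal totals, median-ratio scaling and leaving out both number-1 libraries were chosen after seeing the data; the other alternatives were planned. The excess of lower over higher calls was not seen without compound raceme 2 or 3 or monomaker 2 or 3, fits with too few calls to judge it. It was kept without compound raceme 1 or monomaker 1 and in the other alternatives that called loci. The causes of the changes below were not tested, except that the stricter filter tests fewer loci (10917) and the absence of a filter more (25440). Leaving out each library in turn gave 6 to 2041 called loci, 6 to 735 higher, 0 to 1306 lower, 6 to 1509 with at least a 2-fold change and 0 to 279 adjacent pairs; the highest values came without monomaker 1, where 607 of the 614 loci kept their call, and 5 to 7 lists passed. Without both number-1 libraries, 1921 loci were called, 664 higher and 1257 lower, 1643 with at least a 2-fold change, with 260 adjacent pairs and 3 lists passing. The filter of 10 FPKM in 3 libraries gave 299 called, 75 higher, 224 lower, 229 with at least a 2-fold change and 20 adjacent pairs. With no filter there were 305 lower, 336 with at least a 2-fold change and 11 adjacent pairs, among 413 called. Quantile normalization gave 222 higher, and equal totals 26 adjacent pairs. Adjacent pairs rise with the number of calls and were not set against shuffles in these alternatives. With an estimated correlation, 0 lists passed camera.

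The labels do not say that the library numbers pair the samples, and the values do not settle it. Deviations from the cultivar means correlated at 0.0275, 0.0580 and 0.103 for numbers 1, 2 and 3, and not every sample correlated best with its own number, compound raceme 2 doing so with monomaker 1 (0.101). The second principal component had the number-1 libraries highest (22 and 48.9) and the number-3 libraries lowest (-30.4 and -28.8) in both cultivars. With the number as a replicate block, limma called 0 loci, so 0 higher, 0 lower, 0 with at least a 2-fold change and 0 adjacent pairs, with 4676 loci at an unadjusted p below 0.05 against 4835 without it, and 5 lists passed camera.

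Some results not called with all libraries changed sign in places. SP had a log2 fold change of -1.26 to 0.38 with a library left out and 0.96 without both number-1 libraries. The mean log2 of the glycoalkaloid list ran from -0.57 to 0.35 with a library left out and was 0.34 without both number-1 libraries. For the homeobox list it ran from -0.78 to -0.0431 and was 0.26, for the sugar list it ran from -0.0346 to 0.30, and for the flavonoid list from -1.30 to -0.13, where camera's direction relative to other loci changed in some fits. These lists passed camera in 1 alternative each (glycoalkaloid and flavonoid without monomaker 3, adjusted p = 0.0172 and 0.0382; homeobox without compound raceme 2, adjusted p = 0.0380), except sugar, which passed in 0. With the replicate block, camera's direction for the sugar list changed at a mean log2 of 0.0863. Among the comparisons of named genes with alternatives, 403 kept their side of the threshold, 177 lost a call and 2, both of SP, changed sign. Without counts, the part of the spread due to depth cannot be given.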

Other observations

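Several short lists add to the picture of the buds. HSP17.8 (Solyc06g076520), a small heat shock protein gene, had 15.2, 15.3 and 16.2 FPKM in compound raceme and 12.9, 1.6 and 0 FPKM in monomaker (adjusted p = 0.156 in limma), and the heat shock factor gene HSFB1 (Solyc02g090820) had 65.4 ± 14.3 and 28.1 ± 17.1 FPKM (adjusted p = 0.108). Both were called higher without monomaker 1 and without both number-1 libraries, and in no other alternative. The ethylene synthesis gene ACO1 (Solyc07g049530), in the ripening list, had 15.5, 24.1 and 97.5 FPKM in compound raceme and 14, 6.13 and 8.35 FPKM in monomaker (adjusted p = 0.153). Of 3 tested ripening, 3 gibberellin, 4 light and clock and 3 housekeeping genes, 0 were called by limma. Over all loci 614 of 18802 were called, so 0 among so few genes says little about these lists. GAST1 (Solyc02g089350), a gibberellin-responsive gene, had 90.3 ± 41.7 FPKM in compound raceme and 190 ± 59.4 FPKM in monomaker (adjusted p = 0.165). The second tested trichome gene, MYC1 (Solyc08g005050), had 22.5 ± 2.95 and 16.3 ± 6.14 FPKM (adjusted p = 0.299).

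Of all loci, 1097 were listed at 0 in every compound raceme library and 931 in every monomaker library. Of these, 42 and 26 had a mean of at least 1 FPKM in the other cultivar, and 9 and 3 of them were called.

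Of the tests below, the splits of the samples, the exchange of labels and the wrong label of monomaker 1 were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 called as many loci as the cultivars, the cultivars' own, with 614; the highest other split called 0. With 10 splits the share cannot go under 0.05.

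The lower cell cycle genes may reflect fewer dividing cells in the compound raceme buds, a difference of cultivar or of bud stage that was not tested. Scaling of the FPKM values was argued against, since the weakest median log2 fold change of the 10 genes over 3 scalings was -1.60, with 6 genes called under each. A different share of green leaf tissue was tested with the photosynthesis level as a covariate. The median log2 fold change was -1.48 (median SE 0.48) against -1.68 without it. For the covariate fit, limma's fry, a rotation test, gave a p-value of 0.0445, close to its threshold. The fold was therefore not removed by the measured level. That level itself differs between the cultivars (8.05 against 9.85) and measures leaf tissue only roughly. The test therefore cannot decide whether leaf tissue is the whole cause. The covariate left 3 residual degrees of freedom and ended all 6 calls and every other call in the table, so the part played by tissue stays open.

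Monomaker 1 lay closer to the compound raceme libraries than monomaker 2 and 3 did. A swap with a compound raceme library was argued against, because the 3 of the 10 splits above that make such an exchange gave 0 called loci in limma, against 614; these add no test of their own. Compound raceme RNA mixed into it was tested at 8 loci with at least 5 FPKM in every compound raceme library and a mean of at most 0.2 FPKM over monomaker 2 and 3. The median level of monomaker 1 there was 0.903% of that of compound raceme, which argues against mixing at a share of 10% or more. However, 3 of the 8 loci were at 10% or above. The highest was at 52.6%, below the lowest median of a compound raceme library (86.1%), each set against the other two at loci chosen without it. This argues against monomaker 1 being a compound raceme library under a wrong label, while a library from outside the series was not tested. A bud stage or growing condition nearer to compound raceme may account for its place and was not tested.

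Neighbouring loci called together may point to blocks of the genome that differ between the cultivars, or to tandem copies that share reads or regulation. Many long blocks over the genome were argued against, since pairs 5 to 10 loci apart numbered 108 against a mean of 115.7 in 2000 shuffles (one-sided permutation p = 0.784). This sum over all chromosomes could miss a single long block. Adjoining windows of 20 loci on chromosome 4, from Solyc04g076240 to Solyc04g076800, held 5 and 4 called loci of both directions. They were not tested as a block. Pairs 1, 2 and 3 loci apart were at 2.06, 1.89 and 1.49 times the shuffled mean, and those 5 to 10 apart at 0.933 times. Tandem copies, short blocks and single long blocks were not tested and stay open.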
